A study of Mus musculus with 24 samples.

How the data were processed

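Bulk RNA sequencing was done on Treg sorted from mouse spleen, in 24 libraries from 12 animals. Per the labels, RNA was purified with the RNeasy Micro Kit Plus and checked on a Bioanalyzer Pico chip, messenger RNA was enriched, and paired-end reads were sequenced on an Illumina HiSeq instrument. Libraries were grouped by the subset named in their titles, and animals were numbered as in the titles. For the Nrp1-/ITGB7- libraries the titles number the animals 7 to 12, while the descriptions carry numbers lower by 1. The column names of the deposited table equal the descriptions, so each column belongs to a single library, and no per-sample column was left unmapped. The titles were followed for the animal of each library. The deviations of the 2 libraries of an animal from their group means correlated across genes at 0.36 to 0.66 in animals 1 to 6 and at 0.23 to 0.86 in animals 7 to 12. Each Nrp1+ library correlated best with the Nrp1- library of its own animal, and the reverse match was not tested. The margin was narrow in animals 8, 11 and 12, at 0.82, 0.6 and 0.62 against 0.8, 0.58 and 0.6 for the best other animal. Genes are not independent replicates in these correlations. B cell and myeloid transcripts differed widely between animals and were not removed first. A shared level of these transcripts can thus raise the correlations without the libraries coming from the same animal. Pairing by the description numbers gave 0.8, -0.49, -0.08, 0.49 and 0.58 for the 5 pairs that share a number. No library was a copy of another: the lowest chi-square per gene between libraries was 10.3, against a median of 70.6 within groups.

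The deposited table gives FPKM values that the authors computed from read counts per gene, for 54532 Ensembl genes. Per the submitters' processing notes the tools were HISAT2 2.1.0, featureCounts 1.5.0-p3, DESeq and DESeq2 1.14.1, and the genome build and annotation are not given in the sources used here. Whether the libraries keep strand is not stated either, so reads of overlapping or antisense genes could not be told apart. Gene names and positions were taken from GENCODE M21 on GRCm38, in which 54409 identifiers had a symbol and 54495 a length. The FPKM values could be turned back into reads, since each value of a gene is a whole multiple of what 1 read is worth. With annotated exon lengths 27308 of the 28181 genes above 0 (96.9%) came out whole within a tolerance of 0.02 reads, and 842 more did so with a common divisor of their own values. The other 31 genes held 7.2% of the reads. Reads per library ranged from 13828869 to 21963924. The depth terms in the deposited values equalled median-of-ratios size factors up to a constant (largest relative difference 1.3e-15) and stood at 0.91 to 1.046 of the read totals. The deposited values therefore already carried this scaling, and a log2 fold change of 0 means no change relative to the median-of-ratios reference. FPKM summed to between 418167 and 547484 per library.

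The design written before the data were examined assumed read counts, and named for the case of other values limma on log2(value + 1) with the same samples and terms. That fallback was used. Genes with at least 10 recovered reads in at least 6 libraries of a comparison were tested with limma 3.58.1 (R 4.3.3, intensity trend and robust empirical Bayes) on log2(FPKM + 1), with the animal as a block and Benjamini-Hochberg adjustment at 0.05. The OX40 and ITGB7 comparisons were each fitted on their own 12 libraries. The difference of their effects was fitted on all 24 libraries, since its contrast spans both sets of animals. The overlap of calls was set against the product of the list lengths over the number of genes tested in both. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

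A set of 22 gene lists was fixed before the data were examined. They cover sorting markers, the Treg signature, resting or central Treg genes, effector Treg genes, suppressor molecules, cell cycle, TCR-induced genes, the NF-kB and TNF receptor family, integrins and homing receptors, helper lineage genes, apoptosis and survival, p53 target genes, interferon-stimulated genes, glycolysis, cholesterol synthesis, dissociation and sorting stress, and markers of conventional CD4 T cells, CD8 T and NK cells, B cells, plasma cells, myeloid and dendritic cells, and red cells and platelets. Lists overlap: the effector list shares 10 genes with the suppressor list, 7 with the Treg signature and 7 with the helper list, and 8 of the 15 conventional CD4 T cell markers are also on the resting list. Each list was tested with camera of limma (preset correlation 0.01), with adjusted p over the 22 lists of a comparison. Camera with an estimated correlation and fry were run as alternatives. None of the lists passed with an estimated correlation in either comparison, and 8 did for the difference.

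The text names genes by a rule fixed at the same time. It takes the 5 sorting markers, and the 5 largest rises and falls among genes past the threshold with a mean of at least 10 CPM (counts scaled to the library total) and the same sign in 6 of 6 animals. It adds the 2 members of each list with the smallest p past the threshold. For the difference it takes the 5 smallest adjusted p in each direction. Predicted genes, antigen receptor segments and genes without a symbol were left out. The rule gave 44, 38 and 10 genes, 68 in all, of which some are not reported here.

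The procedure was tested on simulated reads with 200 changed genes, 50 at each fold. All genes of a comparison were drawn with a single dispersion, the median over genes with many reads. Genes of wider spread were thus not represented, and the shares and false calls may be too favourable. In the OX40 comparison (13309 genes) 24%, 80%, 92% and 98% of genes changed by a ratio of 5 to 4 and by 1.5, 2 and 4 times were recovered, with 11 false calls. In the ITGB7 comparison (13520 genes) the shares were 32%, 74%, 86% and 98% with 7 false calls, and for the difference (14424 genes) 12%, 58%, 78% and 88% with 5. Alternatives tried were other scalings (upper quartile, recovered read totals), other pseudocounts (0.1 and 0.5), limma-voom on the recovered reads, no filter and a stricter filter of 1 CPM in 6 libraries, a minimum log2 fold change of 1, no block, a block by description numbers, each animal left out, a marker score as a covariate, the animals split by their B cell and myeloid transcripts, and the lists without the genes that define the gates. That score was the mean log2(FPKM + 1) of the 45 B cell and myeloid markers tested.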

Results

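Messenger RNA was sequenced from regulatory T cells (Treg, the CD4 T cells that express the transcription factor Foxp3 and restrain other immune cells) sorted from the spleens of 12 mice. The mice carried a green fluorescent reporter of Foxp3 and the act-mOVA transgene, which encodes a membrane-bound form of ovalbumin. Treg were separated by surface neuropilin-1 (Nrp1), a receptor widely used as a marker of Treg that arise in the thymus, together with a second protein. In animals 1 to 6 the second protein was OX40, the TNF receptor family member encoded by Tnfrsf4, and each animal gave an Nrp1+/OX40bright and an Nrp1-/OX40dim library. In animals 7 to 12 it was integrin beta 7 (ITGB7), an integrin chain used in homing to the gut, and each animal gave an Nrp1+/ITGB7+ and an Nrp1-/ITGB7- library. The 4 groups thus held 6 libraries each, 24 in all. Each library held between 13828869 and 21963924 reads assigned to genes, and 28181 of the 54532 listed genes had a value above 0 in at least 1 library. Expression is given in FPKM (fragments per kilobase of transcript, scaled for depth), as mean ± SD over the 6 animals of a group. Fold changes are on the log2(FPKM + 1) scale within animals, which understates changes of weakly expressed genes. Gene positions refer to the mouse assembly GRCm38.

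The study concerns the loss of host Treg that carry Helios and Nrp1 around stem cell transplantation. The comparison of Nrp1+/OX40bright with Nrp1-/OX40dim Treg asks how the transcripts of these subsets of the same animal differ. Nrp1 and OX40 change together between them, so the part of each cannot be told apart. As lists, effector Treg genes were higher and resting or central Treg genes lower in Nrp1+/OX40bright Treg (camera adjusted p = 1.08e-19 and 1.22e-10). With an estimated correlation neither list passed, at adjusted p of 0.068 and 0.091. Penk, which encodes the precursor of the enkephalin peptides, stood at 213 ± 24.4 FPKM in Nrp1+/OX40bright Treg and at 5.48 ± 2.41 in Nrp1-/OX40dim Treg (SD, n = 6 each), a log2 fold change of 5.11. The chemokine receptor gene Ccr8 (269 ± 55.2 against 10.8 ± 3.77 FPKM) rose by 4.55, and Pdcd1, which encodes the inhibitory receptor PD-1 (181 ± 72.9 against 12.4 ± 5.59 FPKM), by 3.76. Ly6c1, which encodes a Ly6C surface antigen, fell by 3.45 on the log2 scale, from 393 ± 83.7 FPKM in Nrp1-/OX40dim to 36.6 ± 12.4 in Nrp1+/OX40bright Treg. Each of these differences had the same sign in 6 of 6 animals, with limma adjusted p of 7.8e-07 for Penk, 4.92e-08 for Ccr8, 7.81e-08 for Pdcd1 and 1.39e-05 for Ly6c1.

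The transcripts of the sorting markers followed the gates. Nrp1 (ENSMUSG00000025810, chromosome 8, 128358604 to 128503363) stood at 25.8 ± 1.82 FPKM in Nrp1+/OX40bright and 6.54 ± 0.635 in Nrp1-/OX40dim Treg, a log2 fold change of 1.83 ± 0.07 (SE). Tnfrsf4 (ENSMUSG00000029075, chromosome 4, 156013843 to 156016612) stood at 1460 ± 223 and 349 ± 83.2 FPKM, a log2 fold change of 2.08 ± 0.06. Both genes define the gates, so these differences describe the sort. Itgb7 fell by 0.40 on the log2 scale (352 ± 30 against 464 ± 35.8 FPKM, lower in 6 of 6 animals, limma adjusted p = 0.00609). Foxp3 (52.2 ± 13 against 53.3 ± 9.12 FPKM) and Cd4 (93.9 ± 8.44 against 82 ± 6.9 FPKM) did not pass the threshold, with limma adjusted p of 0.68 and 0.105 and higher values in 2 and 5 of 6 animals. Cd4 passed under upper-quartile scaling (log2 fold change 0.28, limma adjusted p = 0.0286), with limma-voom (0.19, 0.0408) and without animal 6 (0.25, 0.0424).

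**Figure D1:**
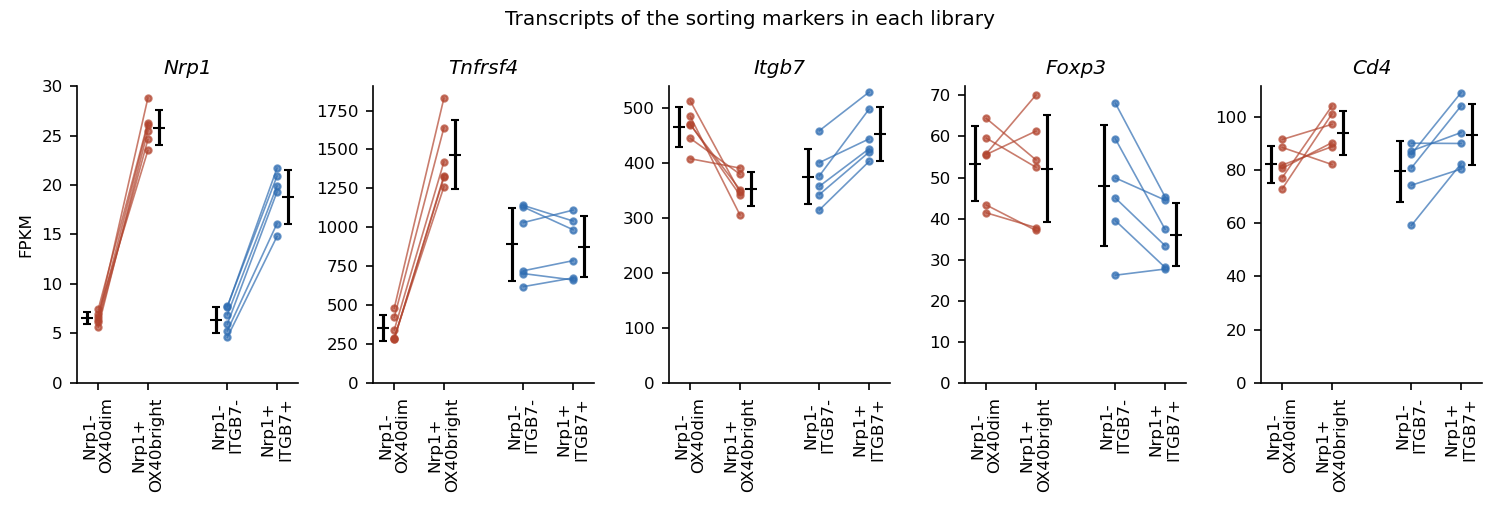
FPKM (y axis, linear, from 0) of the sorting marker genes in each of the 24 libraries, with lines joining the libraries of an animal, red for animals 1 to 6, blue for animals 7 to 12, and black bars giving mean ± SD of 6 libraries. Nrp1 was higher on the Nrp1+ side in every animal of both comparisons, and Tnfrsf4 rose in the OX40 comparison from 349 to 1460 FPKM while standing at 890 and 875 FPKM in the ITGB7 comparison.

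Among the genes with the largest rises were also Il1r2, a decoy receptor for interleukin-1 (chromosome 1, 40074079 to 40125231; 44.1 ± 34.6 against 1.78 ± 0.94 FPKM, log2 fold change 3.83), and the actin gene Actg2 (30.5 ± 2.07 against 2.53 ± 0.834 FPKM, 3.19). Penk lies on chromosome 4 (4133531 to 4138819), Ccr8 on chromosome 9 (120092114 to 120094906), Pdcd1 on chromosome 1 (94038305 to 94052553), Actg2 on chromosome 6 (83512905 to 83536265) and Ly6c1 on chromosome 15 (75044018 to 75048830), and each is annotated as protein coding. The largest falls after Ly6c1 were those of the guanylate-binding protein gene Gbp2b (0.802 ± 0.324 against 12.8 ± 2.7 FPKM, log2 fold change -2.94), Dapl1 (13.3 ± 11.5 against 75.6 ± 15.3 FPKM, -2.81) and Igfbp4, which encodes an insulin-like growth factor binding protein (5.89 ± 2.91 against 38.5 ± 8.42 FPKM, -2.61). Ngp, a neutrophil granule protein gene, had a log2 fold change of -2.57 with a wide spread (156 ± 315 against 406 ± 560 FPKM). Its limma adjusted p of 0.027 rose to between 0.0549 and 0.0704 when animal 2, 3, 4 or 6 was left out. Actg2, Ly6c1 and Gbp2b have close relatives in the genome, and reads shared with those could have been split between them.

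Over all 13309 genes tested, 4176 changed at a limma adjusted p under 0.05, of which 2186 were higher and 1990 lower in Nrp1+/OX40bright Treg. The median size of these changes was 1.31-fold, and 388 genes changed by at least 1 on the log2 scale, 282 upward and 106 downward. With upper-quartile scaling the split was 2839 higher against 1278 lower, or 69% higher in place of 52.3%.

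Most of the effector Treg genes were higher. Of 33 tested members 29 were higher and none lower, also when adjusted over the list alone (camera adjusted p = 1.08e-19). The adjusted p was 0.068 with an estimated correlation. Of 25 Treg signature genes 19 rose and 2 fell (20 and 2 adjusted over the list alone, camera adjusted p = 9.11e-12, and adjusted p = 0.068 with an estimated correlation). Tnfrsf9, which encodes the costimulatory receptor 4-1BB, rose by 2.92 (263 ± 33.8 against 34 ± 5.5 FPKM), and Ikzf2, which encodes Helios, rose by 1.79 (30.3 ± 7.74 against 7.99 ± 2.2 FPKM). Of 21 suppressor molecule genes 15 rose, Penk and Pdcd1 among them, and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 1.02e-09, and adjusted p = 0.068 with an estimated correlation). Of 24 genes of the NF-kB and TNF receptor family 16 rose and 1 fell (17 and 1 adjusted over the list alone, camera adjusted p = 8.57e-08, and adjusted p = 0.091 with an estimated correlation). The Treg signature holds Nrp1 and Tnfrsf4, and the NF-kB list Tnfrsf4. Without these gate genes both lists still passed (camera adjusted p = 5.33e-10 and 7.04e-07, and adjusted p = 0.074 and 0.093 with an estimated correlation). TCR-induced genes, those switched on by the T cell antigen receptor, had 11 of 18 higher and 3 lower, the same when adjusted over the list alone (camera adjusted p = 0.000313, and adjusted p = 0.16 with an estimated correlation). Helper lineage genes had 11 of 15 higher and 2 lower, again the same when adjusted over the list alone (camera adjusted p = 1.57e-05, and adjusted p = 0.091 with an estimated correlation).

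Genes of resting or central Treg moved the other way, with 17 of 20 lower and 1 higher (18 and 1 adjusted over the list alone, camera adjusted p = 1.22e-10, and adjusted p = 0.091 with an estimated correlation). The chromatin organiser gene Satb1 fell by 1.5 (3.59 ± 0.835 against 11.8 ± 1.23 FPKM) and the transcription factor gene Foxp1 by 0.75 (11.8 ± 1.59 against 20.4 ± 1.92 FPKM). Conventional CD4 T cell markers, 8 of which are also on the resting list, had 13 of 14 lower and none higher (14 lower adjusted over the list alone, camera adjusted p = 5.33e-10, and adjusted p = 0.091 with an estimated correlation), and Cd40lg among them fell by 0.98. Cholesterol synthesis genes had 16 of 21 lower and none higher (18 lower adjusted over the list alone, camera adjusted p = 1.12e-06, and adjusted p = 0.16 with an estimated correlation). Sqle, which encodes squalene epoxidase, fell by 0.86 (2.14 ± 0.699 against 4.6 ± 0.666 FPKM). Interferon-stimulated genes had 17 of 30 lower and 5 higher (17 and 6 adjusted over the list alone, camera adjusted p = 0.00219, and adjusted p = 0.29 with an estimated correlation). Gbp2 fell by 1.03 and Iigp1 by 0.87.

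Cell cycle genes had 8 of 33 higher and none lower, 5 of them adjusted over the list alone (camera adjusted p = 0.0028, and adjusted p = 0.48 with an estimated correlation). Tyms, needed for thymidylate synthesis, rose by 0.65 and the replication licensing gene Mcm6 by 0.61. The list did not pass in animals 5 and 6 alone (median log2 fold change -0.01, camera adjusted p = 0.953), a fit with 1 residual degree of freedom. Nor did the list pass with the B cell and myeloid marker score as a covariate (0.04, camera adjusted p = 0.421). The lists of sorting markers (2 higher, 1 lower of 5), apoptosis and survival (10 and 4 of 28), p53 target genes (7 and 2 of 21), glycolysis (7 and 4 of 20) and integrins and homing receptors (11 and 10 of 33) did not pass camera, and neither did the dissociation and sorting stress list (5 and 6 of 20). Their camera adjusted p were 0.064, 0.0639, 0.064, 0.064, 0.634 and 0.52. Adjusted over the list alone these counts were 2 and 1, 10 and 4, 7 and 2, 9 and 4, 11 and 11, and 5 and 8. Leaving out an animal brought the sorting marker list under 0.05 without animal 1 or 6 (camera adjusted p of 0.0482 and 0.0469). Without Nrp1 and Tnfrsf4 its camera adjusted p was 0.656. The apoptosis list passed without animal 1, 2 or 5 (0.0482, 0.0364 and 0.0442). In animals 1 to 4 alone the sorting marker, apoptosis, p53 and glycolysis lists passed (camera adjusted p of 0.0406, 0.0406, 0.0441 and 0.0406). These 4 lists also passed without a filter (0.0298, 0.0325, 0.0325 and 0.043), and the sorting marker and apoptosis lists with limma-voom (0.0317 and 0.0391) and the marker covariate (0.0227 and 0.0446). The sorting marker list passed without a block as well (0.0382). Single members still changed. Bcl2a1d, a survival gene with near-identical copies that could share its reads, rose by 2.34. The p53 targets Pmaip1 and Sesn2 rose by 0.89 and 0.8, the lactate transporter gene Slc16a3 and the glycolytic gene Tpi1 by 1.13 and 0.84, and the integrin gene Itgb8 by 1.35. On the stress list Dusp1 rose by 1.07 and Socs3 fell by 1.29.

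Markers of other cell types were present. B cell markers had 7 of 20 lower and none higher in Nrp1+/OX40bright Treg (8 lower adjusted over the list alone, camera adjusted p = 0.0189, and adjusted p = 0.38 with an estimated correlation), with Bank1 at -0.43 and Fcrla at -0.28. The list did not pass without animal 5 (camera adjusted p = 0.0775) or in animals 1 to 4 alone (median -0.10, camera adjusted p = 0.291), nor without a block (0.743) or with the marker covariate (0.239). Myeloid and dendritic cell markers had 5 of 24 lower and 2 higher, S100a8 falling by 1.27 and Zbtb46 rising by 0.29. CD8 T and NK cell markers had 4 of 15 lower and 3 higher, with Cd8a at -0.66 and the perforin gene Prf1 at -1.8. Of the plasma cell markers 1 of 12 rose, Prdm1, a regulator that effector Treg also express (log2 fold change 0.66). Of the red cell and platelet markers 1 of 13 fell, Hba-a1 (-0.51), whose limma adjusted p of 0.0284 rose to between 0.0769 and 0.087 without animal 1, 2, 3 or 5 and whose reads could be shared with a near-identical haemoglobin gene. Camera adjusted p for the myeloid, CD8 and NK, plasma cell and red cell lists were 0.273, 0.476, 0.064 and 0.476, and the plasma cell list passed without animal 1 (0.0371). In animals 1 to 4 alone the myeloid list (median -0.22) and the plasma cell list passed, at camera adjusted p of 0.0406 and 0.0426. The plasma cell list also passed with limma-voom (0.0317), without a filter (0.0325) and with the marker covariate (0.0496). Adjusted over the list alone they had 2 higher and 4 lower, 3 and 4, 1 and 0, and 0 and 0 members changed.

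The mean log2(FPKM + 1) of 45 B cell and myeloid markers was lower by 0.16 ± 0.11 on the Nrp1+/OX40bright side (SD, 6 of 6 animals). It was between 5.49 and 5.73 in the 4 libraries of animals 5 and 6 against 3.06 to 3.78 in animals 1 to 4. Animals 1 to 4 alone gave 3562 changed genes and animals 5 and 6 alone 711, the latter with 1 residual degree of freedom. These sets share no library, and their log2 fold changes had a Pearson correlation of 0.74 across genes, which are not independent replicates. With the marker score as a covariate 1014 genes passed, and the median standard error grew 1.98-fold. Of the 44 genes chosen for naming in this comparison 12 then lost their call. Among them were Itgb7 (log2 fold change -0.43, limma adjusted p = 0.189), Dapl1 (-2.83, 0.173) and Prf1 (-1.74, 0.0576).

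**Figure D2:**
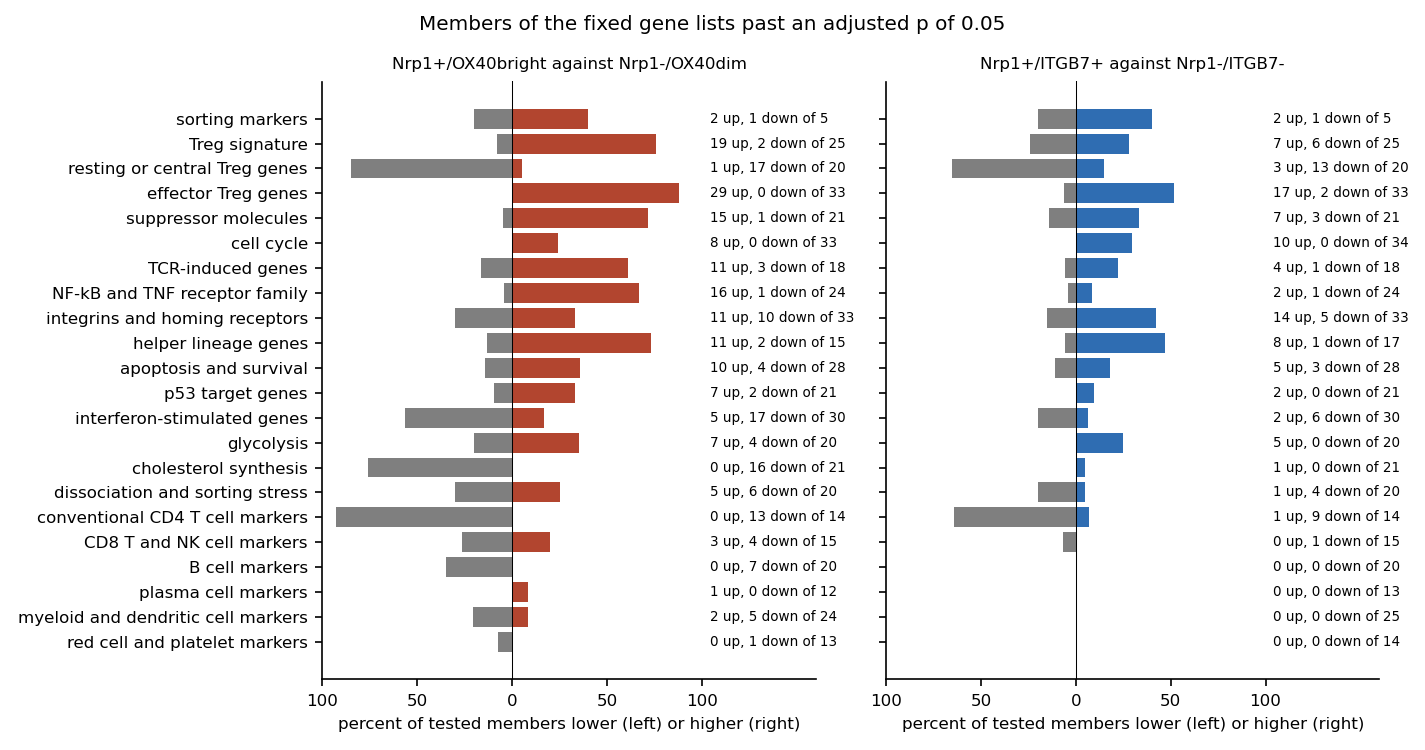
Percent of the tested members of each of the 22 gene lists that were lower (grey, left) or higher (coloured, right) at an adjusted p under 0.05, for the OX40 comparison (left panel) and the ITGB7 comparison (right panel), with the counts beside each bar. Effector Treg genes had 29 of 33 members higher in the left panel and 17 of 33 in the right panel, and cholesterol synthesis genes 16 of 21 lower in the left panel and none lower in the right panel.

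The comparison of Nrp1+/ITGB7+ with Nrp1-/ITGB7- Treg puts the same question to Nrp1+ Treg that carry the gut-homing integrin chain. Nrp1 and ITGB7 change together between these subsets, so the part of each cannot be told apart. Here effector Treg genes and integrins and homing receptors were higher as lists and resting or central Treg genes lower (camera adjusted p = 1.76e-09, 0.00036 and 3.51e-06). None of these passed with an estimated correlation, at adjusted p of 0.13, 0.13 and 0.18. Actg2 stood at 23.4 ± 4.17 FPKM in Nrp1+/ITGB7+ and 4.05 ± 0.791 in Nrp1-/ITGB7- Treg (SD, n = 6 each), a log2 fold change of 2.27. Itgb1, the integrin beta 1 gene (50.5 ± 7.41 against 14.4 ± 2.62 FPKM), rose by 1.74, and S100a6, which encodes a calcium-binding protein (484 ± 67.4 against 168 ± 16.8 FPKM), by 1.52. Ly6c1 fell by 1.65 (103 ± 36.4 against 315 ± 64.1 FPKM) and Igfbp4 by 1.53 (9.94 ± 2.75 against 30 ± 4.68 FPKM). Each had the same sign in 6 of 6 animals, with limma adjusted p of 3.21e-05 for Actg2, 3.56e-06 for Itgb1, 3.55e-05 for S100a6 and 4.58e-05 for both Ly6c1 and Igfbp4.

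Of the sorting markers, Nrp1 stood at 18.8 ± 2.76 FPKM in Nrp1+/ITGB7+ and 6.35 ± 1.3 in Nrp1-/ITGB7- Treg, a log2 fold change of 1.44 ± 0.05 (SE). Itgb7 (ENSMUSG00000001281, chromosome 15, 102215995 to 102231944) differed less, at 452 ± 49.2 against 374 ± 50.6 FPKM, a log2 fold change of 0.28 ± 0.05 or 1.21-fold (higher in 6 of 6 animals, limma adjusted p = 0.00707). Tnfrsf4 stood at 875 ± 193 against 890 ± 236 FPKM (log2 fold change -0.01, higher in 3 of 6 animals, limma adjusted p = 0.923). Cd4 had a log2 fold change of 0.23 (higher in 5 of 6 animals, limma adjusted p = 0.0576), and passed with limma-voom (0.0103) and without animal 8 (0.0489). Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245) fell by 0.37, from 48 ± 14.8 to 36.1 ± 7.75 FPKM (lower in 5 of 6 animals, limma adjusted p = 0.0353). This call was lost without animal 7, 8, 10 or 11, at limma adjusted p between 0.0904 and 0.103 and log2 fold changes between -0.36 and -0.31. It was also lost without a filter or a block (limma adjusted p of 0.122 and 0.426), settings that cannot alter the log2 fold change of -0.37. In animals 7 and 8 alone, with 1 residual degree of freedom, it was -0.61 (0.11), and in animals 9 to 12 alone -0.25 (0.234). With the replicate block by description numbers neither Itgb7 (0.33, limma adjusted p = 0.174) nor Foxp3 (-0.23, 0.421) passed. The call of Itgb7 was also lost without a block (0.28, limma adjusted p = 0.169).

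The remaining genes with the largest rises were Zbtb32, a zinc finger transcription factor gene (9.55 ± 3.19 against 2.16 ± 0.369 FPKM, log2 fold change 1.7), and the mitotic cyclin gene Ccnb2 (19.7 ± 7.22 against 8.17 ± 5.87 FPKM, 1.52). The call of Ccnb2 was lost without animal 8, 10, 11 or 12, at limma adjusted p between 0.0575 and 0.0733. Dapl1 (-1.15), the matrix metalloproteinase gene Mmp9 (-1.09, 9.08 ± 6.95 against 18.3 ± 12.4 FPKM) and Apol9b (-1.05), which has a close relative that could share its reads, completed the largest falls. Itgb1 lies on chromosome 8 (128685654 to 128733200), S100a6 on chromosome 3 (90612882 to 90624181), Zbtb32 on chromosome 7 (30589681 to 30598909), Ccnb2 on chromosome 9 (70407692 to 70421547) and Igfbp4 on chromosome 11 (99041244 to 99054392). Over all 13520 genes tested, 1622 changed at a limma adjusted p under 0.05, 910 higher and 712 lower, with a median size of 1.27-fold. Of these, 29 rose and 10 fell by at least 1 on the log2 scale. With the replicate block by description numbers 185 genes changed, and 20 of the 38 genes chosen for naming in this comparison lost their call.

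Effector Treg genes had 17 of 33 members higher and 2 lower (19 and 2 adjusted over the list alone, camera adjusted p = 1.76e-09, and adjusted p = 0.13 with an estimated correlation). S100a6 was among them, and Lgals1, which encodes galectin-1, rose by 1.17 (919 ± 154 against 408 ± 61.7 FPKM). Resting or central Treg genes had 13 of 20 lower and 3 higher (14 and 4 adjusted over the list alone, camera adjusted p = 3.51e-06, and adjusted p = 0.18 with an estimated correlation), Ly6c1 and Igfbp4 among those that fell. Conventional CD4 T cell markers had 9 of 14 lower and 1 higher (11 and 1 adjusted over the list alone, camera adjusted p = 1.84e-06, and adjusted p = 0.13 with an estimated correlation), including Igfbp4 and Dapl1. Integrins and homing receptors had 14 of 33 higher and 5 lower (18 and 7 adjusted over the list alone, camera adjusted p = 0.00036, and adjusted p = 0.13 with an estimated correlation), with the chemokine receptor gene Ccr2 rising by 0.75. This list holds the gate gene Itgb7, and without it the camera adjusted p was 0.000962. Helper lineage genes had 8 of 17 higher and 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 5.88e-05, and adjusted p = 0.13 with an estimated correlation), with Rora rising by 0.89 and Pdcd1 by 0.79. Glycolysis genes had 5 of 20 higher and none lower (8 higher adjusted over the list alone, camera adjusted p = 0.00251, and adjusted p = 0.13 with an estimated correlation), with Tpi1 rising by 0.45 and Pgam1 by 0.31. Cell cycle genes had 10 of 34 higher and none lower (14 higher adjusted over the list alone, camera adjusted p = 2.67e-07, and adjusted p = 0.36 with an estimated correlation), with the proliferation marker gene Mki67 rising by 0.55 and Mcm6 by 0.34. With the replicate block by description numbers the cell cycle median was 0.06 (camera adjusted p = 0.176), and Mki67 and Mcm6 did not pass (limma adjusted p = 0.157 and 0.219).

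Treg signature genes went both ways, 7 of 25 higher and 6 lower (9 and 6 adjusted over the list alone, camera adjusted p = 0.181), with Ikzf2 rising by 0.54 (21.4 ± 5.48 against 14.2 ± 3.13 FPKM). Suppressor molecules had 7 of 21 higher and 3 lower (8 and 3 adjusted over the list alone, camera adjusted p = 0.0974), and Areg, which encodes the tissue repair factor amphiregulin, rose by 0.74. TCR-induced genes (4 higher, 1 lower of 18), the NF-kB and TNF receptor family (2 and 1 of 24), interferon-stimulated genes (2 and 6 of 30) and cholesterol synthesis genes (1 and 0 of 21) did not pass camera. Their camera adjusted p were 0.648, 0.676, 0.897 and 0.23, and adjusted over the list alone the counts were 4 and 3, 2 and 1, 3 and 6, and 1 and 0. The TCR-induced list had a median of -0.02 and a mean of 0.04, and the interferon list a median of 0.03 with a test pointing downward. Members that changed were Cd5 (0.34), Tnfaip3 (0.23), Icam1 (0.24) and the interferon-stimulated genes Ifi27l2a (0.88) and Oas1a (0.77). Tnfaip3 lost its call without animal 9 or 10 (limma adjusted p of 0.054 and 0.0644), and Icam1 without animal 8, 10, 11 or 12 (0.0629 to 0.0937). Apoptosis and survival genes (5 higher, 3 lower of 28), p53 target genes (2 and 0 of 21) and stress genes (1 and 4 of 20) did not pass either, at camera adjusted p of 0.493, 0.648 and 0.163, with 5 and 3, 4 and 4, and 1 and 4 adjusted over the list alone. Among them Bcl2a1d rose by 0.61, Pmaip1 by 0.43 and Sesn2 by 0.33, and Hsp90aa1 fell by 0.37 and Socs3 by 0.6. The mean log2(FPKM + 1) of the stress genes was lower on the Nrp1+/ITGB7+ side in 6 of 6 animals, with a mean difference of -0.1 ± 0.04 (SD). Sesn2 lost its call without animal 8, 11 or 12 (limma adjusted p 0.051 to 0.0673). The sorting marker list had 2 of 5 higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.0392, and adjusted p = 0.36 with an estimated correlation). It did not pass without animal 10, 11 or 12 (camera adjusted p of 0.0571, 0.0503 and 0.0906), or without the gate genes Nrp1 and Itgb7 (0.933). With the replicate block by description numbers the Treg signature, suppressor and apoptosis lists passed (camera adjusted p of 0.0103, 0.0242 and 0.041).

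B cell markers had a median log2 fold change of -0.28 with 0 of 20 members changed, also when adjusted over the list alone (camera adjusted p = 0.00609, and adjusted p = 0.64 with an estimated correlation). Without animal 9 the median was -0.11 (camera adjusted p = 0.165), and in animals 7 and 8 alone it was 0.07 (camera adjusted p = 0.0792). CD8 T and NK cell markers had 1 of 15 lower, Prf1 (-0.86), also when adjusted over the list alone (camera adjusted p = 0.00708, and adjusted p = 0.49 with an estimated correlation), and in animals 7 and 8 alone their median was -0.03 (camera adjusted p = 0.927). None of 13 plasma cell, 25 myeloid and dendritic cell and 14 red cell and platelet markers changed, by limma over all genes or adjusted over the list alone. Their camera adjusted p were 0.648, 0.153 and 0.347, and the myeloid list passed without animal 8 (median -0.20, camera adjusted p = 0.00655). It also passed with limma-voom (-0.21, 0.0046) and in animals 9 to 12 alone (-0.22, 0.001). With the replicate block by description numbers the plasma cell (-0.62, camera adjusted p = 0.0182), myeloid (-0.64, 4.05e-05) and red cell (-0.51, 0.00862) lists passed. That block joins the Nrp1+ library of animal 8 with the Nrp1- library titled animal 9. Their B cell and myeloid marker scores were 3.25 and 5.88, so a difference in level between animals enters these falls. The B cell and CD8 and NK lists did not pass without a block (0.492 each) or with the marker covariate (0.363 and 0.0984). The B cell and myeloid marker score lay between 2.95 and 3.25 in the 4 libraries of animals 7 and 8 and between 4.96 and 6.19 in those of animals 9 to 12. It was lower on the Nrp1+/ITGB7+ side in 5 of 6 animals by a mean of 0.18 ± 0.41 (SD), most of it from animal 9 (-0.93). Without animal 9 the mean difference was -0.03 ± 0.21. Animals 9 to 12 alone gave 529 changed genes and animals 7 and 8 alone 17, the latter with 1 residual degree of freedom. Between these sets the Pearson correlation of log2 fold changes was 0.47 across genes, which are not independent replicates. Leaving out animal 8 gave 949 genes and leaving out animal 10 gave 973.

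**Figure D3:**
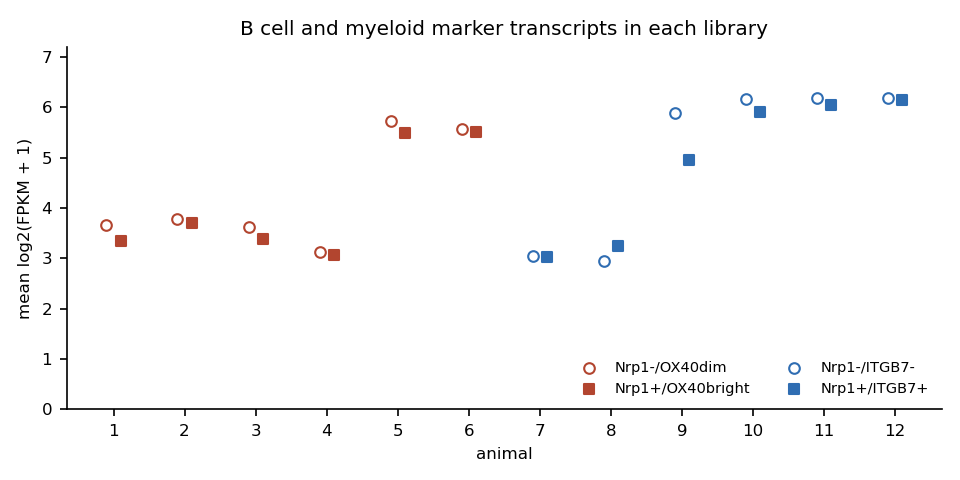
Mean log2(FPKM + 1) of 45 B cell and myeloid marker genes (y axis, from 0) in each of the 24 libraries by animal (x axis), with open circles for Nrp1- and filled squares for Nrp1+ libraries, red for the OX40 and blue for the ITGB7 comparison. Both libraries of animals 5, 6 and 9 to 12 lay between 4.96 and 6.19, and those of animals 1 to 4, 7 and 8 between 2.95 and 3.78.

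The 2 comparisons share no animal or library, so the overlap of their calls could be set against that of independent lists. Actg2, Nrp1, Ikzf2, Pdcd1 and Bcl2a1d rose in both, and Ly6c1, Igfbp4, Dapl1, Socs3 and Prf1 fell in both. Of 12970 genes tested in both, 570 rose in both against 148 for independent lists, and 440 fell in both against 107 (one-sided Fisher's exact test over genes, p = 3.25e-242 and 4.2e-194). This test treats genes as independent, which they are not, so its p do not measure repetition over animals. Both comparisons also share the Nrp1 gate. Opposite calls were made for 56 genes, 25 higher with OX40bright and lower with ITGB7+ (115 for independent lists) and 31 the reverse (138). Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.51 and a Spearman correlation of 0.49. The same-direction overlap of 1010 genes was 11 in animals 1 to 4, 7 and 8 alone, 189 in animals 5, 6 and 9 to 12 alone, 661 without animal 8 and 653 without animal 10.

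**Figure D4:**
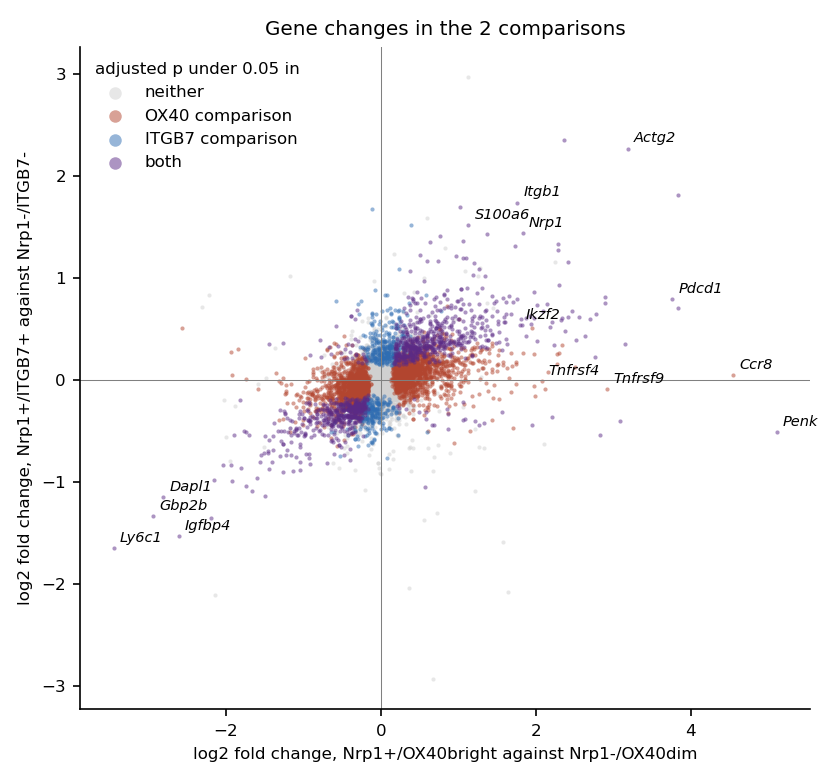
Log2 fold change of each of 12970 genes in the OX40 comparison (x axis) and in the ITGB7 comparison (y axis), coloured by the comparison in which the limma adjusted p was under 0.05. Ly6c1, Igfbp4 and Dapl1 lie at the lower left, Actg2 at the upper right, and Penk, Ccr8 and Tnfrsf9 far to the right near or below 0 on the y axis.

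The effects of the 2 comparisons were then tested against each other in a single model of all 24 libraries. As a list, effector Treg genes had a larger upward effect with OX40bright (camera adjusted p = 3.03e-15, and adjusted p = 0.018 with an estimated correlation). Penk rose by 5.11 in the OX40 comparison and fell by 0.51 in the ITGB7 comparison (115 ± 25 against 167 ± 47.5 FPKM, lower in 6 of 6 animals, limma adjusted p = 0.00614). The difference of its effects was 5.62 on the log2 scale (limma adjusted p = 1.85e-09). Ccr8 (170 ± 38 against 171 ± 66.1 FPKM in the ITGB7 comparison) had a difference of 4.5 (limma adjusted p = 9.44e-10), and Tnfrsf9 (137 ± 20.3 against 148 ± 38.2 FPKM) a difference of 3.01 (limma adjusted p = 1.63e-09). Tnfrsf4, the gene of the OX40 gate, had a difference of 2.1. Nrn1, which encodes neuritin, rose in 6 of 6 animals of each comparison, from 2.89 ± 0.362 to 21.9 ± 1.94 FPKM with OX40bright and from 5.19 ± 0.735 to 8.48 ± 0.955 FPKM with ITGB7+, a difference of 1.94.

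In the other direction the differences with the smallest adjusted p were those of Chil5 (-2.15), Prg4 (-1.8), Slfn1 (-1.16), Thada (-0.88) and Gbp2b (-1.61), with limma adjusted p of 6.53e-08, 2.49e-07, 9.39e-07, 2.72e-06 and 5.22e-06. Chil5, a chitinase-like gene, was lower with OX40bright in 6 of 6 animals (3.56 ± 0.894 against 15.4 ± 3.07 FPKM) and higher with ITGB7+ in 5 of 6 (16.1 ± 2.96 against 12.8 ± 1.76 FPKM). Prg4, which encodes a lubricating proteoglycan, was lower with OX40bright in 6 of 6 animals (5.79 ± 0.973 against 17.8 ± 4.12 FPKM) and higher with ITGB7+ in 6 of 6 (10.1 ± 2.45 against 7.74 ± 2 FPKM). Slfn1 and Thada were lower with OX40bright in 6 of 6 animals and stood at 51.1 ± 4.03 against 53.6 ± 9.48 and 10.3 ± 2.12 against 11.3 ± 2.08 FPKM in the ITGB7 comparison. Gbp2b was lower on the Nrp1+ side in 6 of 6 animals of each comparison. Of 14424 genes tested, 1831 differed at a limma adjusted p under 0.05, 1000 upward and 831 downward, and 206 by at least 1 on the log2 scale. With upper-quartile scaling 71% of the differing genes lay upward in place of 54.6%. In animals 1 to 4, 7 and 8 alone 447 genes differed and in animals 5, 6 and 9 to 12 alone 284. The differences in these sets had a Pearson correlation of 0.47 across genes, which are not independent replicates.

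By gene list, the effect was larger upward with OX40bright for the Treg signature (18 of 25 members with a difference above 0 and none below, camera adjusted p = 1.65e-20), effector Treg genes (21 and 3 of 33, 3.03e-15), suppressor molecules (13 and 2 of 21, 1.27e-11), the NF-kB and TNF receptor family (13 and 0 of 24, 6.06e-13) and TCR-induced genes (8 and 1 of 18, 4.16e-06). It was larger downward for resting or central Treg genes (14 of 20 below 0 and none above, camera adjusted p = 6.61e-11), conventional CD4 T cell markers (10 of 14, none above, 6.44e-09) and cholesterol synthesis genes (13 of 21, none above, 1.72e-11). These 8 lists held with an estimated correlation, at adjusted p of 0.0028, 0.018, 0.0031, 0.0039, 0.026, 0.031, 0.029 and 0.0059 in the order given. Without the gate genes the Treg signature and NF-kB lists still passed (camera adjusted p = 6.28e-18 and 1.92e-11, and adjusted p = 0.0031 and 0.0053 with an estimated correlation). Interferon-stimulated genes (12 of 30 below 0 and none above, camera adjusted p = 1.67e-05), helper lineage genes (4 above and 2 below of 18, 0.0455) and apoptosis and survival genes (5 of 28 above, none below, 0.0314) did not, at adjusted p of 0.077, 0.28 and 0.077 with an estimated correlation. The helper list also missed the threshold without animal 1, 2, 3, 7, 8 or 12 (camera adjusted p 0.0505 to 0.0758), under upper-quartile (0.0746) or read-total scaling (0.0589), without a block (0.17) and in animals 5, 6 and 9 to 12 alone (0.476). The apoptosis list missed it without animal 3 or 12 (0.0559 and 0.0506) and in animals 5, 6 and 9 to 12 alone (0.0771). Adjusted over the list alone, the counts above and below 0 of the 11 lists were 21 and 1, 23 and 4, 14 and 2, 15 and 0, 10 and 1, 0 and 15, 0 and 10, 0 and 17, 3 and 15, 6 and 3, and 5 and 0.

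The other 11 lists did not pass camera for the difference. Among 34 cell cycle genes no member differed by limma, over all genes or adjusted over the list alone (camera adjusted p = 0.179, and 0.00932 with a median of -0.17 without animal 9). The cell cycle list passed in animals 1 to 4, 7 and 8 alone (median -0.08, camera adjusted p = 0.00765) and in animals 5, 6 and 9 to 12 alone (-0.23, 0.0053). Integrins and homing receptors had 6 of 33 members above 0 and 13 below (9 and 14 adjusted over the list alone, camera adjusted p = 0.0644). This list passed without animal 3 or 11, at 0.0334 and 0.0403. It also passed with upper-quartile scaling (0.0312), read-total scaling (0.0288), limma-voom (0.0417), no filter (0.0313) and no block (0.0281). So it did with the marker covariate (0.0456) and in animals 5, 6 and 9 to 12 alone (0.0255), but not without Itgb7 (0.123). The p53 target genes had 4 of 21 above 0 and none below (5 and 0 adjusted over the list alone, camera adjusted p = 0.0779), and passed without animal 6 or 9, at 0.0477 and 0.0459, without a filter (0.0313) and in animals 1 to 4, 7 and 8 alone (0.0276). Of 13 plasma cell markers 1 lay above 0, also when adjusted over the list alone (camera adjusted p = 0.0697), and the list passed without animal 1, 7 or 8, at 0.0373, 0.0491 and 0.0472, with limma-voom (0.0196), without a filter (0.0313) and with the marker covariate (0.0371). None of 20 B cell markers differed by limma, over all genes or adjusted over the list alone (camera adjusted p = 0.45, and 0.0479 without animal 8), and their median of 0.09 was -0.28 in animals 1 to 4, 7 and 8 alone (camera adjusted p = 0.0159). The sorting markers (2 above and 1 below of 5), glycolysis genes (1 and 2 of 20), stress genes (3 and 4 of 20) and CD8 T and NK cell markers (2 and 1 of 15) had camera adjusted p of 0.0862, 0.939, 0.948 and 0.304. The sorting markers passed without a filter (0.0363) and in animals 1 to 4, 7 and 8 alone (median 0.56, camera adjusted p = 0.00648). Without the gate genes 2 sorting markers were left, with a median of 0.14 and a camera adjusted p of 0.638. Adjusted over the list alone the counts of the sorting marker, glycolysis, stress and CD8 T and NK lists were 3 and 1, 3 and 3, 5 and 4, and 2 and 1. Myeloid and dendritic cell markers had 1 of 25 above 0 and red cell and platelet markers none of 14, also when adjusted over the list alone (camera adjusted p of 0.868 and 0.924). In animals 5, 6 and 9 to 12 alone the myeloid list passed (median 0.28, camera adjusted p = 0.0255). The myeloid list had a median of 0.07, a mean of -0.05 and a test pointing upward, and the stress list a median of 0.01, a mean of 0.05 and a test pointing downward.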

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

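The counts over other splits of the libraries, the tests of the difference of effects and the fits without single animals, without a block or with the block by description numbers were planned. The other tests in this part were chosen after the result was seen. Of 100 splits of the 12 libraries of animals 1 to 6 into equal groups, the real split included, only 1, the real split, gave as many genes as the 4176 of the OX40 comparison, and the highest of the others gave 1. For the ITGB7 comparison the count was again 1 of 100, with 1622 genes for the real split and 383 for the highest other, which parted the libraries of animals 8 to 11 as their groups do. Among the 32 splits that part all 6 pairs, the highest other split gave 0 genes in each comparison by limma. For the difference of effects, 1 of 100 splits of the 12 animals, the real one, gave as many genes as the 1831 found, and the highest other gave 1. The 3 counts were thus not reached by any other split tried. In a wrong split a real difference enters the residual spread and lowers the count, and only 32 splits part all 6 pairs. The splits therefore cannot exclude chance.

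Transcripts of B cells and myeloid cells were high in both libraries of animals 5, 6 and 9 to 12, in a sort gated on the Foxp3 reporter. Median FPKM over the libraries of these animals against those of animals 1 to 4, 7 and 8 was 921 against 76.3 for Cd79a, 21100 against 1370 for Igkc, 6410 against 668 for Cd74, 1070 against 60.6 for Lyz2 and 1570 against 51.9 for S100a8. Over all libraries, the first principal component (the axis of most variation) held 49.7% of the variance. In absolute value it correlated at 1 (rounded) with the B cell and myeloid marker score and at 0.03 with the Nrp1 side. The second component held 13.2% and correlated at 0.88 with the Nrp1 side. Read depth was argued against as a cause of the high transcripts, as the ratio of the median read totals was 1.07. A panel of 12 pan-T-cell genes had a median log2 difference of -0.33 between these animals and the rest, lower in 12 of 12, which is consistent with cells or RNA of other types in the sorted samples. The labels give no group that could explain it biologically, and no such explanation was tested.

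Foxp3 was lower in Nrp1+/ITGB7+ than in Nrp1-/ITGB7- Treg, with log2 differences of -0.65, -0.58, -0.16, -0.42, -0.48 and 0.08 in animals 7 to 12. Dilution by B cells and myeloid cells was argued against, as the 12 pan-T-cell genes had a median log2 fold change of 0.12. Resting conventional CD4 T cells in the Nrp1+/ITGB7+ libraries were only weakly argued against as the whole cause. The effector list rose in this comparison and shares 7 genes with the Treg signature. Such rises could hold the median of the Treg signature up, so a part for these cells stays open. The other 23 Treg signature genes without Nrp1 had a median of 0.04 (SD 0.35, 11 below 0), which lies 0.4 above Foxp3. Il2ra, Il2rb and Gpr83 were among those below 0, and Tigit, Nt5e and Ikzf4 among those above. Of 14 conventional CD4 T cell markers 12 lay below 0, with a median of -0.38. Since 8 of these markers are also on the resting list, they cannot show whether activated conventional CD4 T cells were present. A difference between the subsets in Foxp3 transcript may remain as a hypothesis, for a call that was lost without animal 7, 8, 10 or 11 (limma adjusted p of 0.0904, 0.103, 0.0962 and 0.0932, log2 fold changes of -0.31, -0.33, -0.36 and -0.35, lower in 4 of 5 animals each). The call was also lost with the block by description numbers (-0.23, limma adjusted p = 0.421) and without a block (-0.37, 0.426).

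Itgb7 transcript differed 1.21-fold between libraries sorted as positive and negative for its protein, with log2 differences of 0.15, 0.2, 0.4, 0.25, 0.3 and 0.36 in animals 7 to 12. Its call was lost with the block by description numbers (0.33, limma adjusted p = 0.174) and without a block (0.28, 0.169). RNA of other cell types diluting the difference was argued against, since animals 7 and 8, with the lowest marker scores, had differences of 0.15 and 0.2. Libraries swapped between the sides were argued against by Nrp1, whose lowest log2 difference was 1.33. A surface level set partly after transcription could leave such a small difference, and this was not tested.

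Single samples that stood apart from the other 5 of their group numbered 10 among 130 groups of values tested, where chance gives 6.5. The Nrp1+/OX40bright library of animal 3 held 22.0 M reads (M, megareads) against 14.5 to 16.1 in the others, and the Nrp1+/ITGB7+ library of animal 9 held 19.9 M reads against 14.2 to 15.5. In the OX40 comparison the log2 difference of Ly6c1 was -4.61 in animal 2 and -3.40 to -3.03 in the others. Tyms stood at 0.34 in animal 6 against 0.66 to 0.82, Dusp1 at 1.48 in animal 4 against 0.88 to 1.07, and Bank1 at -0.77 in animal 5 against -0.43 to -0.29. In the ITGB7 comparison Pdcd1 stood at 1.09 in animal 10 against 0.67 to 0.76. Animal 9 had a median of -0.11 over the cell cycle list against 0.27 to 0.42, -1.41 over plasma cell markers against 0.01 to 0.37, and -0.67 over myeloid and dendritic cell markers against -0.08 to 0.14.

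The effects of the 2 comparisons differed by a test of the difference itself, limma for genes and camera for lists. Ccr8 differed by 4.5, Nrn1 by 1.94, Tnfrsf9 by 3.01, Penk by 5.62 and Tnfrsf4 by 2.1 on the log2 scale, and Chil5 by -2.15, Prg4 by -1.8, Slfn1 by -1.16, Thada by -0.88 and Gbp2b by -1.61. The median difference was 0.76 over the Treg signature, -0.46 over resting or central Treg genes, 0.68 over effector Treg genes, 0.64 over suppressor molecules, 0.42 over TCR-induced genes and 0.35 over the NF-kB and TNF receptor family. It was 0.11 over helper lineage genes, 0.08 over apoptosis and survival genes, -0.28 over interferon-stimulated genes, -0.38 over cholesterol synthesis genes and -0.47 over conventional CD4 T cell markers. The helper lineage, apoptosis and interferon lists did not pass with an estimated correlation (adjusted p = 0.28, 0.077 and 0.077 with an estimated correlation). The helper list was also lost without animal 1, 2, 3, 7, 8 or 12 and the apoptosis list without animal 3 or 12. The gates of the comparisons differ, and so do the animals, and the part of each in these differences was not tested.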

How the results depend on the processing

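The pseudocounts, the scaling to read totals, the marker covariate, the splits by B cell and myeloid transcripts and the lists without gate genes were chosen after seeing the data, and the other alternatives were planned. Count tests on raw counts were not run, since the table holds FPKM, and median-of-ratios scaling was not run, since the deposited values already carry it. The counts of 4176, 1622 and 1831 genes (OX40, ITGB7, difference) and the overlap of 1010 stayed within 1.5 times under other scalings, pseudocounts and limma-voom. Counts under upper-quartile scaling were 4117, 1564 and 1809, and under limma-voom 4635, 2150 and 2006. Under upper-quartile scaling the median of all genes was 0.04 in place of -0.01 in the OX40 comparison and 0.06 in place of 0.01 for the difference.

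Without a filter more genes entered the adjustment, and 789 genes changed in the ITGB7 comparison with an overlap of 506. With a minimum log2 fold change of 1 the counts were 388, 39 and 206 and the overlap 27. With no replicate block they were 2771, 454 and 833, and the overlap 306. A replicate block by description numbers gave 185 genes in the ITGB7 comparison and an overlap of 148 on 5 pairs, and 20 of 38 named genes lost their call. That block joins the Nrp1+ library of animal 8 with the Nrp1- library titled animal 9, with marker scores of 3.25 and 5.88. With the marker covariate 1014 genes passed in the OX40 comparison and the overlap was 373. The log2 fold changes correlated across genes, which are not independent replicates, at 0.91 with those of the fit without it, and the median standard error grew 1.98-fold. Animals with low B cell and myeloid transcripts alone gave 17 genes in the ITGB7 comparison (2 animals), 447 for the difference and an overlap of 11. Those with high transcripts alone gave 711, 529 and 284 genes and an overlap of 189, with fewer animals in each fit. In the first set the median of the B cell markers turned from -0.28 to 0.07 in the ITGB7 comparison and from 0.09 to -0.28 for the difference, and the cause was not tested.

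Camera with an estimated correlation left 0 of 12 lists in the OX40 comparison, 0 of 10 in the ITGB7 comparison and 8 of 11 for the difference, while fry called 17, 13 and 13. At an unadjusted p under 0.05 the genes numbered 5572, 3717 and 3632. Leaving out each animal gave 3255 to 3922 genes in the OX40 comparison, 949 to 1435 in the ITGB7 comparison, 1491 to 1789 for the difference and an overlap of 653 to 991, with 949 reached without animal 8 and 653 without animal 10. The lists past the threshold then numbered 12 to 15, 9 to 11 and 9 to 13. Over all alternatives the named genes kept side and direction in 728 of 792 results in the OX40 comparison, 594 of 722 in the ITGB7 comparison and 239 of 240 for the difference. In 61, 126 and 1 results the call was lost, in 3, 2 and 0 it was gained, and no named gene reversed. For the gene lists 388 of 418, 417 of 440 and 510 of 550 results kept both. These list totals leave out camera with an estimated correlation and fry. They include the minimum log2 fold change, which cannot alter a list result. Without the gate genes 12, 9 and 11 lists passed, and the sorting marker list of the ITGB7 comparison, then of 3 genes, had a median of -0.01 and no longer passed. Of simulated genes changed by a ratio of 5 to 4, 24%, 32% and 12% were recovered in data with 200 changed genes. The adjustment is stricter there than with the counts found, so these shares do not give the detection limit of the real data.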

Other observations

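The gene families in this part were chosen after the data were seen, and adjusted p are over 34 families in each comparison. None of these families passed with an estimated correlation in either comparison. Genes with symbols of cytosolic ribosomal proteins were lower on the Nrp1+ side. The family was taken by symbol, so pseudogenes that share reads with their parent genes could be among its members. In the OX40 comparison 63 of 181 were lower and 3 higher (median log2 fold change -0.26, camera adjusted p = 1.23e-07). In the ITGB7 comparison 78 of 185 were lower and 1 higher (median -0.28, camera adjusted p = 1.78e-22). With an estimated correlation neither passed (adjusted p = 0.66 and 0.32). Mitochondrially encoded genes were also lower in the ITGB7 comparison, 5 of 17 with none higher (median -0.26, camera adjusted p = 0.00129, and adjusted p = 0.42 with an estimated correlation), and did not pass in the OX40 comparison (median -0.11, 0.661). Ly6 family genes, which encode small membrane-anchored proteins, had 7 of 9 lower in the OX40 comparison (median -0.65, camera adjusted p = 0.000613) and 3 of 9 lower in the ITGB7 comparison (median -0.37, 0.000439), with none higher (adjusted p = 0.25 and 0.17 with an estimated correlation). Guanylate-binding protein genes, induced by interferon, had 7 of 10 lower and 1 higher in the OX40 comparison (median -0.49, camera adjusted p = 0.00043) and 4 of 10 lower and none higher in the ITGB7 comparison (median -0.17, 0.000439). With an estimated correlation the adjusted p were 0.66 and 0.37. S100 genes, which encode calcium-binding proteins, had 5 of 9 higher and 2 lower in the OX40 comparison (median 0.52, camera adjusted p = 0.0285) and 6 of 9 higher and none lower in the ITGB7 comparison (median 0.54, 1.89e-06). With an estimated correlation the adjusted p were 0.63 and 0.17. Annexin genes had 5 of 9 higher and none lower in the ITGB7 comparison (median 0.22, camera adjusted p = 0.000492, and adjusted p = 0.17 with an estimated correlation) and 3 of 10 higher and 1 lower in the OX40 comparison (median 0.06, 0.275). Genes of TNF ligands had 6 of 6 higher in the OX40 comparison (median 0.61, camera adjusted p = 0.00043) and 2 of 7 in the ITGB7 comparison (median 0.15, 0.0254), at adjusted p of 0.25 and 0.36 with an estimated correlation. Those of the NR4A and EGR factors, induced early after antigen receptor signals, had 5 of 6 higher in the OX40 comparison (median 0.70, camera adjusted p = 0.00043, and adjusted p = 0.28 with an estimated correlation) and 2 of 6 in the ITGB7 comparison (median 0.15, 0.0703). Variable segments of the T cell receptor alpha chain had 15 of 69 higher in the OX40 comparison (median 0.31, camera adjusted p = 0.00043) and 9 of 69 in the ITGB7 comparison (median 0.21, 2.54e-06), with none lower (adjusted p = 0.22 and 0.17 with an estimated correlation). Those of the beta chain went both ways in the OX40 comparison, 5 of 22 higher and 6 lower (median -0.11, camera adjusted p = 0.651), and had 5 of 22 higher and none lower in the ITGB7 comparison (median 0.19, 0.000439, and adjusted p = 0.4 with an estimated correlation). For the difference of effects 6 of the 22 beta segments lay below 0 and none above (median -0.19, camera adjusted p = 0.0147, and adjusted p = 0.61 with an estimated correlation). Each of these medians kept its sign under upper-quartile scaling and under scaling to read totals.

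Members of the Treg signature that moved with or against Foxp3 in the ITGB7 comparison were also chosen after their values were seen. Il2ra, which encodes the alpha chain of the interleukin-2 receptor (CD25), stood at 17.4 ± 3.59 FPKM in Nrp1+/ITGB7+ and 28.2 ± 6.19 in Nrp1-/ITGB7- Treg (log2 fold change -0.66, lower in 6 of 6 animals, limma adjusted p = 0.0004). Il2rb, its beta chain, fell by 0.44 (lower in 6 of 6 animals, limma adjusted p = 0.00302) and Gpr83 by 0.41 (lower in 6 of 6 animals, limma adjusted p = 0.0276). Tigit, which encodes an inhibitory receptor, rose by 0.60, Nt5e, which encodes the ectonucleotidase CD73, by 0.60, and Ikzf4, a relative of Helios, by 0.53. These rises were seen in 6 of 6 animals each, with limma adjusted p of 0.00335, 0.00143 and 0.00467. The Nrp1- groups, from different mice, stood at 349 ± 83.2 FPKM (OX40dim) and 890 ± 236 FPKM (ITGB7-) for Tnfrsf4, a difference that was not tested.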
